A study of Homo sapiens with 2 samples.

How the data were processed

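Gene expression was measured in MCF-7, an established human breast cancer cell line that grows as oestrogen-receptor-positive luminal epithelium, after 72 h with 5-aza-2'-deoxycytidine (Aza, decitabine), a cytidine analogue that traps DNA methyltransferases and thereby lowers CpG methylation in dividing cells. Each of 2 two-colour Phalanx oligonucleotide arrays carried Aza-treated RNA labelled with Cy3 in channel 1 and RNA of untreated MCF-7 labelled with Cy5 in channel 2, per the labels. One array held the 5 µM dose and the other the 10 µM dose. There was 1 array per dose, and no array had the dyes swapped. The samples were grouped by the treatment label. The free-text sample description speaks of aerobic control RNA sampled over minutes, which matched no other label and was not used.

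The scanner files, as deposited, give the fluorescence intensity of each spot and of its local background in both channels, as whole scanner units up to the scanner's ceiling, with no normalization. Per the file headers they also hold the percent of a spot's pixels that lie over 2 SD above the local background, the percent of saturated pixels, and a spot flag. Each array has 39200 spots, of which 30968 hold 1 human probe each, 1079 hold 148 repeated control probes and 7153 are empty. The value table deposited by the authors holds log2 ratios for the 30968 human probes. The method of its normalization is not given in the sources used here. Set against each array's scanner values, its columns had r = 0.896 (5 µM) and r = 0.947 (10 µM) across probes with the log2 of background-subtracted channel 1 over channel 2, so its direction is Aza over untreated. Its column medians were 0.031 at 5 µM and 0.0072 at 10 µM. How background was treated in it stays unknown. The control probe PH_c_0000001 had 103 spots at a median of 65447 in channel 2 and 30 in channel 1 on the 5 µM array, so the channels are not mixed between the arrays, which gave 65478 and 24 at 10 µM.

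Neither the files nor the reference table used here pairs the probe IDs with genes. No gene is therefore named, and the gene lists that had been chosen in advance were not tested. Results are given by probe. Probe IDs are printed for at most 2 probes in each direction. They were the first 2 in each direction by a rule also set in advance. It takes probes above background in both channels on both arrays and at least 2-fold higher, or lower, on both, ranked by the smaller change of the 2 arrays. Genomic position is not analysed here for the same reason.

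Median foreground and median local background of each spot were corrected with normexp (offset 50) on all spots in R 4.3.3 with limma 3.58.1, and the log2 ratio of Aza over untreated was normalized within each array by loess (span 0.3) with control, empty and flagged spots at weight 0. Positive values mean more signal in Aza-treated RNA. Spots with a negative flag were left out (4599 human probes at 5 µM, 7594 at 10 µM). A probe counted as above background in a channel where at least 50 percent of its pixels lay over 2 SD above local background. The definition was chosen once the file columns were known. It passed 1 and 2 of the 7153 empty spots. It also removed 193 and 108 unflagged probes with over 200 units of signal, for a reason that was not tested. Probes above background in at least 1 channel were compared. The offset shrinks the ratios of dim probes towards 0.

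With 1 array per dose there is no replicate, so the counts per dose describe these arrays by size (at least 2-fold) and carry no p-value. The median SD of repeated spots of 1 control probe, over probes with at least 4 usable spots, was 0.15 on the log2 scale at 5 µM (62 probes) and 0.13 at 10 µM (54 probes). It measures spot-to-spot error only. The number of arrays limits the precision. One supplementary fit used limma on both arrays as 2 treated samples, with a two-sided test of the mean log2 ratio against 0 and Benjamini-Hochberg adjustment over 18328 probes. In it the difference between doses counts as error, and the spread among untreated cultures and any dye effect are left out. Nothing states that the arrays came from separate cultures, so the p-values rest on these 2 samples alone. The standard errors are moderated: limma draws each probe's variance towards one estimated over all probes, with 5.90 prior degrees of freedom. They are therefore not each probe's own spread between the arrays. On simulated arrays with 200 changed probes among 18328, this fit called 100% of the 3-fold and 100% of the 4-fold changes and 20 of 18128 unchanged probes. At least 2-fold on both arrays was reached by 90% of the 3-fold and 98% of the 4-fold changes and by 0 unchanged probes. The changed probes were drawn from those above background in both channels on both arrays, with signals well over the median. The percentages therefore do not hold for dim probes. Noise was drawn separately for each array, with no shared control and no dye effect. Even so, the 20 false calls were a larger share of all calls than the 0.05 aimed at. False calls may be more frequent still if the arrays share a control.

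Alternatives fixed before the data were examined were no background correction, plain background subtraction, median centring in place of loess, the authors' deposited log2 values, no filter on dim probes, a filter on both channels, flagged spots kept, and thresholds of 1.5-fold and 3-fold. Print-tip loess was not run because the files have 1 block. Alternatives added after seeing the data were spot means, normexp without offset, removal of the trend over the array surface (a moving-window median over 12 rows and 14 columns to each side), and a restriction to bright probes, whose background-subtracted signal in both channels was at least 10 times the 99th percentile of the empty spots. Rows of the 5 µM array are called crowded with lower probes where a band of 25 rows held at least 1.5 times its share of them, a limit set after the bands were seen.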

Results

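The data were 2 two-colour arrays that compared MCF-7 cells after 72 h of Aza with untreated MCF-7 cells, at 5 µM on the first array and at 10 µM on the second. The comparison asks which transcripts change when CpG methylation is lowered by the drug. The 5 µM array was the brighter one. On it 24163 of 30968 human probes (78.0%) were above background in at least 1 channel, with a median background-subtracted signal of 396 units in the Aza channel and 365 in the untreated channel. On the 10 µM array 19093 probes (61.7%) were above background, with medians of 217 and 165 units. The Aza channel was at the scanner's ceiling for 250 probes at 5 µM and for 26 at 10 µM, and the ratios of those probes are too small if the signal was cut off. The 10 µM array thus rests on fewer measurable probes and lower signal.

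At 5 µM, 195 probes were at least 2-fold higher in Aza-treated than in untreated cells and 232 were at least 2-fold lower. The higher probe whose smaller change of the 2 arrays was largest, PH_hs_0038991, gave 4585 units in treated and 120 units in untreated cells, a log2 ratio of 4.53, against 5.14 with plain background subtraction and 5.12 in the authors' deposited values. The probe ranked after it, PH_hs_0013028, gave 16910 and 3310 units, a log2 ratio of 2.17. Among the lower probes, PH_hs_0029175 gave 1175 units in treated and 4167 in untreated cells, a log2 ratio of -1.88. The log2 ratio of PH_hs_0024472 was -1.72, from 147 and 595 units. Repeated spots of control probes on the same array had a median SD of 0.15 and a 90th percentile SD of 0.40 on the log2 scale, which covers spot error and not the spread between cultures. There is no replicate of either dose, so no value in the comparisons of single doses has a test.

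The probes lower at 5 µM were concentrated in part of the array. Rows 251 to 325 of 350 held 146 of the 232 lower probes (62.9%) and 20.1% of the probes compared. The median log2 ratio by bands of 25 rows ran from 0.069 to -0.29 at 5 µM and from 0.10 to -0.16 at 10 µM, with the lowest band in the same rows on both arrays. With this trend removed, 201 probes were higher and 137 lower at 5 µM, which moved the share of higher probes from 45.7% to 59.5%. That share was 29.0% with plain background subtraction (384 higher, 940 lower) and 33.2% in the authors' deposited log2 values (429 higher, 865 lower).

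**Figure D1:**
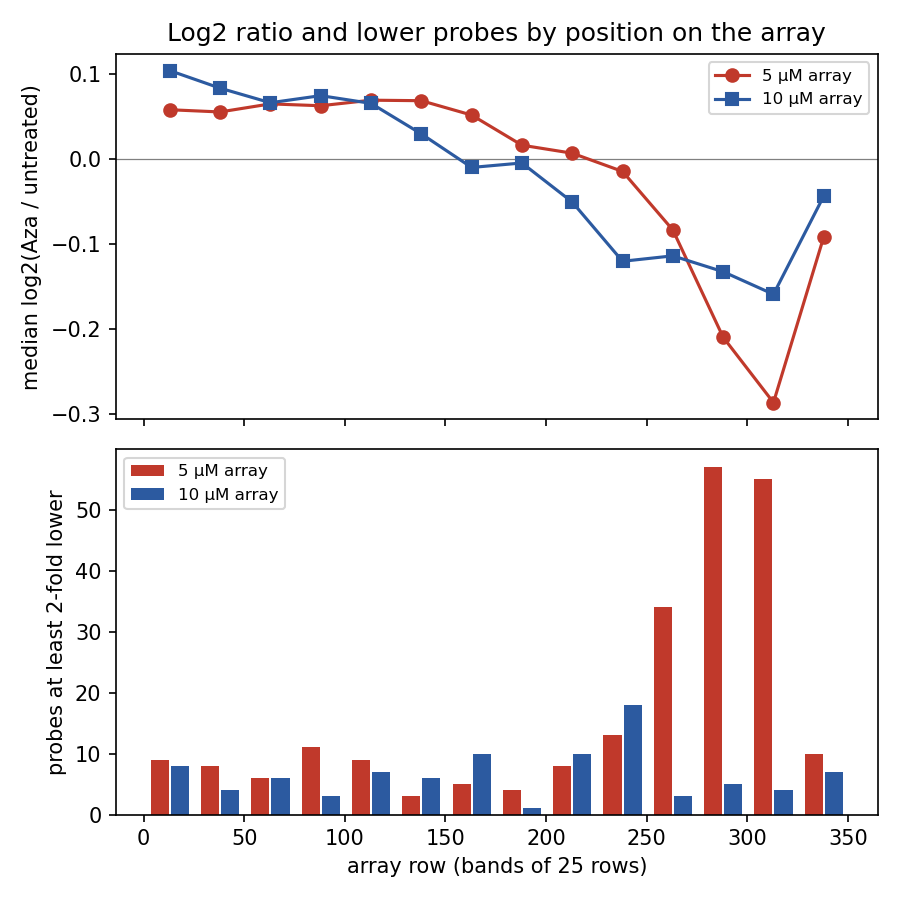
Upper panel, the median log2 ratio of Aza over untreated for probes above background, in bands of 25 array rows, for the 5 µM array (circles) and the 10 µM array (squares). Lower panel, bars give the number of probes at least 2-fold lower in each band. The medians are lowest, -0.29 and -0.16, in rows 301 to 325, and 146 of the 232 lower probes of the 5 µM array lie in rows 251 to 325.

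At 10 µM, 250 probes were at least 2-fold higher and 92 at least 2-fold lower. The log2 ratio of PH_hs_0038991 was 4.09, from 3754 units in treated and 114 in untreated cells. PH_hs_0013028 gave 9823 and 1585 units, a log2 ratio of 2.11. The 2 lower probes were lower here too, PH_hs_0029175 with a log2 ratio of -2.11 and PH_hs_0024472 with -1.40. With plain background subtraction PH_hs_0024472 had a log2 ratio of -2.14 here, and in the authors' deposited values -2.20. Higher probes made up 73.1% of those past the threshold. That share depended on the processing. It was 93.5% with median centring (676 higher, 47 lower), 42.9% with plain background subtraction (641 higher, 852 lower) and 42.5% in the authors' deposited log2 values (636 higher, 859 lower).

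Probes changed in the same direction at both doses were mostly higher. Of 18328 probes above background on both arrays, 98 were at least 2-fold higher on both, 10 were at least 2-fold lower on both, and 0 were past the threshold in opposite directions. The 98 higher probes had a median log2 ratio of 1.46 at 5 µM and 1.37 at 10 µM. The 10 lower probes had medians of -1.57 and -1.20. Among probes above background in both channels on both arrays, 84 were higher and 6 lower. With plain background subtraction the counts were 175 and 165, and in the authors' deposited values 180 and 151. Among the 11918 bright probes, those same settings gave 98 higher and 11 lower, and 99 higher and 11 lower. In each, 74 of the higher and 5 of the lower were among the main 98 and 10, so they are not the same sets. The near balance thus came with the inclusion of dim probes.

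The overlap of higher probes was larger than the chance arrangements tried here gave. Independent lists of the same lengths would share 2.47 higher and 0.71 lower probes. Whether the untreated RNA on both arrays was 1 extract is not given in the sources used here. If it was, the ratios share chance values. In 100 simulations of unchanged samples against 1 shared control, a mean of 1.93 probes (at most 6) were higher on both arrays and a mean of 2.22 (at most 11) were lower on both. The 98 higher probes lie above that range and the 10 lower probes lie within it. The simulated lists were shorter than the observed ones, however. At 5 µM a mean of 12.9 higher and 12.5 lower probes passed the threshold, against 183 and 142 observed. At 10 µM the means were 77.5 and 76.4, against 247 and 91. Only normal noise was simulated, so that range does not bound what noise with more extreme values would give. Neither number shows how much of the overlap is an effect of the drug, since a dye effect on a single probe would also repeat.

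Probes selected at 1 dose were also read at the other. Of 183 probes higher at 5 µM and above background on both arrays, 174 (95.1%) had a positive log2 ratio at 10 µM and 98 (53.6%) were past the threshold there, with a median log2 ratio of 1.06. Of 142 probes lower at 5 µM, 123 (86.6%) had a negative ratio at 10 µM but 10 (7.04%) were past the threshold, with a median of -0.30. Of these 142 probes, 93 lay in rows 251 to 325, and 2 of the 93 and 8 of the 49 elsewhere were past the threshold. The 10 µM array had fewer probes above background in these rows (1014 against 1617 at 5 µM in rows 276 to 300), and the offset shrinks dim ratios. The 2 counts therefore do not show that the row probes failed to repeat. In the simulations of unchanged samples with 1 shared control, the same sign was found for 97.0% of the higher and 96.3% of the lower probes selected at 5 µM, so if the control was shared, sign agreement of the observed size or more can arise with no effect. Probes selected at 10 µM gave 98 of 247 higher probes and 10 of 91 lower probes past the threshold at 5 µM. Of these, 228 (92.3%) and 68 (74.7%) had the same sign at 5 µM, against 94.2% and 93.8% simulated.

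**Figure D2:**
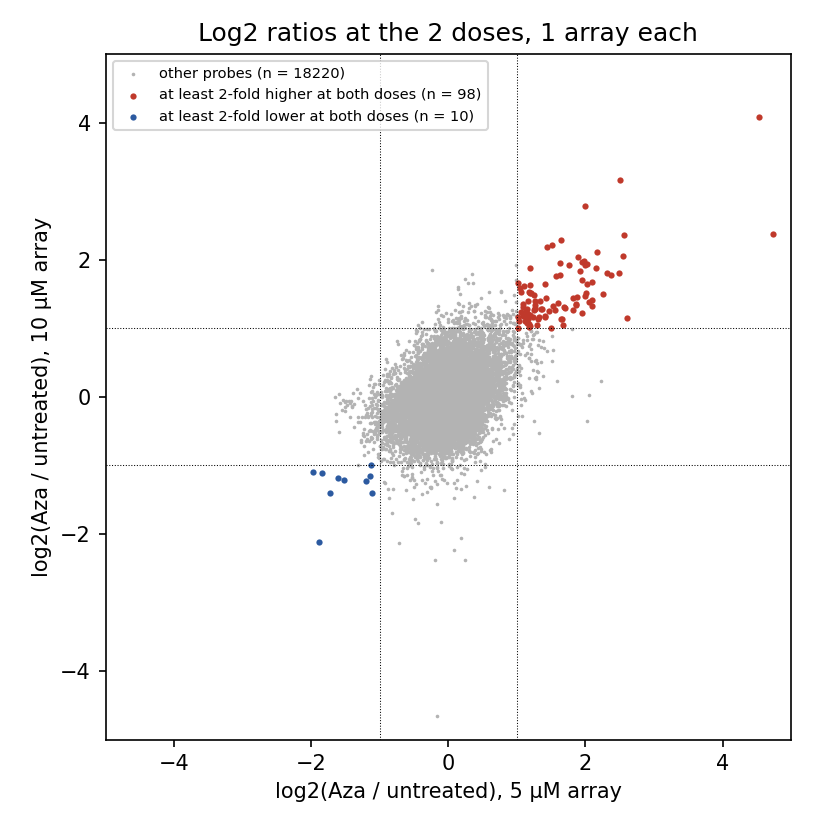
The log2 ratio of Aza over untreated on the 5 µM array (horizontal) against the 10 µM array (vertical), 1 point per probe above background on both arrays, with dotted lines at 2-fold. The 98 probes at least 2-fold higher at both doses lie in the upper right and the 10 lower ones in the lower left, and no probe is past the threshold in opposite directions.

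Which dose had the larger ratio among the probes changed at both depended on the processing. Of the 98 higher probes 42 had the larger ratio at 10 µM, against 56 with plain background subtraction and 54 in the authors' deposited values. Of the 10 lower probes 4 had the larger decrease at 10 µM, against 8 in both of those settings. Over all 18328 probes, 232 had a log2 ratio at least 1 higher at 10 µM than at 5 µM and 135 at least 1 lower. The counts were 560 and 557 with plain background subtraction, and 499 and 611 in the authors' deposited values. The difference between doses had a robust SD of 0.35, against 0.20 for the error of repeated spots in such a difference, and 71.6% of probes differed by less than 2 such errors. With 1 array per dose, a difference between doses cannot be told apart from one between arrays. Across probes, which are not independent replicates, the log2 ratios of both doses correlated with r = 0.42 and rho = 0.34. Unchanged samples, taken as sharing 1 control, gave r = 0.49 in simulation. The covariance was 0.0586, against 0.0493 simulated, a difference of 0.0093. The simulated r was set by giving the control and each treated sample equal variance. The simulated covariance was set by the spread of these same ratios. Neither comparison can therefore decide whether the drug had an effect.

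Some probes were above background in 1 channel only. On both arrays 124 probes were above background in Aza-treated cells and not in untreated cells, and 213 the other way round. Only 4 of the 124 were at least 2-fold higher on both arrays and 3 of the 213 at least 2-fold lower. Each was set against the lowest signal measured above background or the probe's own signal in the dimmer channel, whichever was higher. Whether the other probes of both sets lay near the limit was not tested. The largest change among the 124 was at least 3.50-fold at 5 µM and at least 3.78-fold at 10 µM. Among the 213 it was at least 3.92-fold at 5 µM and at least 2.28-fold at 10 µM.

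Both arrays taken as 2 treated samples gave 111 probes higher and 13 lower in Aza at an adjusted p under 0.05 (limma, two-sided, Benjamini-Hochberg over 18328 probes). Of these, 97 and 10 were also at least 2-fold changed on both arrays. PH_hs_0038991 had an adjusted p of 0.00105 (limma) with a mean log2 ratio whose moderated standard error was 0.18, and it was higher on both arrays. For PH_hs_0013028 and PH_hs_0029175 the adjusted p was 0.00878 (limma), with standard errors of 0.15 and 0.16. For PH_hs_0024472 it was 0.0209 (limma), with a standard error of 0.17. The fit leaves out the spread among untreated cultures and cannot separate the drug from the dye, and its counts were 15 higher and 1 lower without the filter on dim probes, against 610 and 597 in the authors' deposited values and 585 and 643 with plain background subtraction.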

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

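The tests of the surface trend on the probes changed at both doses, and of the share of 10 µM lower probes in rows 251 to 325, were chosen after those results were seen, as was reading the offset and the surface tests against all probes and against the share left in the rows, and the row probes' own 10 µM values. Control probes, which are not among the probes counted but give the SD of repeated spots, carried signal that differed between channels. Of the 148 control probes, 9 were at least 2-fold brighter in the Aza channel on both arrays and 19 at least 2-fold dimmer. The 9 had median log2 ratios of 5.80 at 5 µM and 6.96 at 10 µM. The lowest log2 ratio of any control probe was -9.82 at 5 µM and -10.1 at 10 µM, so some read almost wholly in 1 channel. What the control probes hold is not given in the sources used here.

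More probes were higher than lower at both doses, 98 against 10. The trend over the array surface is argued against, since its removal left 94 higher and 10 lower probes, 91 and 9 of them among the 98 and 10. An offset that holds back dim lower probes stays open, since over all probes normexp without offset gave 144 higher and 92 lower and plain subtraction 175 and 165, while the bright probes, with 98 and 11 under plain subtraction, leave the dim ones out. A dye difference of single probes stays open and cannot be told apart from the treatment, because the number of arrays with swapped dyes is 0. An effect of Aza is the biological explanation that the design names, and it may account for the pattern alone or beside those left open.

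The lower probes of the 5 µM array crowded into rows 251 to 325, where 146 of 232 lay. Uneven signal over the array surface is a candidate explanation for part of this and stays open for the rest. With the trend removed 42 of the 146 stayed past the threshold, but the median log2 ratio of the 146 moved only from -1.12 (quartiles -1.22 and -1.05) to -0.91 (-1.02 and -0.82), so many calls ended because they lay near the threshold. These rows then still held 30.7% of the lower probes (exact 95% interval 23.1 to 39.1%), beside 20.1% of the probes compared. Exact intervals here treat the probes of 1 array as independent, which neighbouring spots may not be. The rows were also picked for their excess of lower probes in these data, so part of a remaining excess may be built in. The ratios of all probes also spread more widely in these rows, with a robust SD of 0.34 against 0.25 elsewhere. With the trend removed it was 0.33 against 0.24. The part of this wider spread in the remaining share was not tested. Probes placed in these rows that respond to Aza stay open too. Of the 92 lower probes at 10 µM, 12 (13.0%, exact 95% interval 6.93 to 21.7%) lay there, beside 16.9% of the probes compared. The adjacent rows 226 to 250 held 18 of the 92, with 1315 of the 19093 probes compared. Higher probes at 10 µM were few in rows 251 to 325 too, so low counts there are not particular to lower probes. The 93 row probes measured at 10 µM had a median of -0.29, with 77 negative (82.8%). The median was -0.13 for all 3088 probes of these rows measured on both arrays and -0.39 for the 49 lower probes elsewhere. Unchanged samples simulated with 1 shared control gave the same sign for 96.3% of lower probes selected at 5 µM. If the control was shared, the sign agreement thus does not speak for a response.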

How the results depend on the processing

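The supplementary fit, the counts and the correlation had 159 alternative values, of which 93 stayed within 1.5 times the main count (0.1 for r) and 66 did not. A single count has no sign to turn, but which direction had more probes turned in every comparison except that of both doses. At 10 µM it turned to more lower probes with plain subtraction, the authors' table and normexp without offset, and by limma with plain subtraction and normexp without offset. Between doses it turned in the authors' table and at 3-fold. At 5 µM it turned to more higher probes with median centring, the filter on both channels, 3-fold, spot means, all settings on bright probes and the surface trend removed. The 8 log2 ratios of the named probes kept their sign in all 64 alternative values, 43 of them within the SD of repeated spots. The widest moves were PH_hs_0024472 at 10 µM, from -1.40 to -2.20 in the authors' table, and PH_hs_0038991 at 5 µM, from 4.53 to 5.14 with plain subtraction. Below, each pair gives probes higher, then lower, and the order is 5 µM, 10 µM, both doses, 10 µM against 5 µM, and limma. The main pairs were 195 and 232, 250 and 92, 98 and 10, 232 and 135, and 111 and 13. Plain background subtraction gave 384 and 940, 641 and 852, 175 and 165, 560 and 557, and 585 and 643. The authors' value table gave 429 and 865, 636 and 859, 180 and 151, 499 and 611, and 610 and 597. Both hold the 98 higher and 10 lower probes of the main setting. Normexp without offset gave 685 lower at 5 µM, 468 and 495 at 10 µM, 92 lower at both, 434 and 367 between doses, and 683 and 692 by limma. Median centring gave 327 higher at 5 µM, 676 and 47 at 10 µM, 159 higher at both, and 5 lower by limma. A 1.5-fold threshold gave 861 and 1416, 1134 and 866, 338 and 148, and 1477 and 1070. A 3-fold threshold gave 51 and 13, 42 and 12, 24 and 1, and 3 and 17. Without the filter on dim probes limma gave 15 and 1. With the filter on both channels 6 were lower at both doses and limma gave 28 lower. Settings on bright probes were added after seeing the data. With the main values 92 were lower at 5 µM and 5 at both doses, and limma gave 371 and 206. With plain subtraction 143 were lower at 5 µM and 147 at 10 µM, and limma gave 374 and 192. With the authors' values 145 and 161 were lower, and limma gave 377 and 200. Removing the surface trend, also added later, gave 137 lower at 5 µM. The cause of these moves was not tested, except that thresholds and filters change the number of probes by construction. No background correction, spots with a negative flag kept and spot means (added later) moved no count by over 1.5 times. The lower signal of the 10 µM array limits what can be called there. Gene lists were not run, since no table pairs probes with genes.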

Other observations

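The hypothesis was set before its result was seen, and its repeat with plain subtraction was added after. If Aza raised mainly transcripts that untreated cells hardly make, the probes higher at 5 µM would rank low in untreated signal, read on the other array so that the same spot's error is not counted in both. The 183 higher probes had a median percentile of 50.1 among the 18328 probes above background on both arrays. Of 10000 random lists of the same size, 52.0% were at or below it. Probes below background on either array are left out of this ranking. The 247 probes higher at 10 µM had a median percentile of 50.9 on the 5 µM array. With plain subtraction the 292 higher probes at 5 µM had a median percentile of 39.6, and 0.01% of random lists were at or below that. By the rule set first, on the main correction alone, the median lay at the middle of the random lists and counted against the hypothesis. Requiring both corrections to give the same answer was decided after both were seen. The offset shrinks the ratios of dim probes and plain subtraction does not, but why the 2 corrections differ here was not tested. The low level in untreated cells may or may not mark the higher probes, and these data leave it open. The 142 lower probes at 5 µM had a median percentile of 41.8 on the 10 µM array, with 2.3% of random lists at or below. However, 93 of them lay in rows 251 to 325, where the 10 µM array had lost measurable probes, and the random lists were not matched by row. A low rank can thus come from position on the array, so nothing is concluded about their level in untreated cells.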
